A study of Mus musculus with 25 samples.

How the data were processed

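The analysis started from the deposited series table of log2 values, which per the submitters' processing notes were made by the authors with RMA in Affymetrix Expression Console 1.1. Per the labels' protocols, thymic iNKT cells were sorted as TCR beta and CD1d tetramer positive and CD24 negative, and divided by CD44 and NK1.1. Per the labels' protocols, RNA was amplified and labelled with NuGEN kits and hybridised to Clariom S mouse arrays. Versions of any other upstream tools are not given in the sources used here. The values ran from 3.04 to 13.7, with array medians between 7.28 and 7.39, and were used as deposited with no further normalization. The genome build is not given in the sources used here, so no coordinates are reported.

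Of 28846 measured items 6640 control items were left out, and 22206 transcript clusters were tested. Of these 19572 carry exactly 1 gene symbol and 2634 none in the probe table used here. For the 55 symbols with more than 1 cluster, the cluster with the highest mean was used. Negative control medians lay between 6.19 and 6.59, and 24.8% of the clusters read above their array's median on no array. Where no array of a group read above it, the log2 difference is given as at least the brighter group's mean minus the dimmer group's mean of the higher of control median and own value, and with both groups low none is given, a rule added after the results were seen. Positive control medians exceeded negative control medians by 3.27 to 3.83 on each array. All 25 arrays were used.

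The groups, comparisons, gene lists, gene naming rule, tests and most of the settings tried were fixed before the data were examined, and further settings concerning mouse sex and replicate numbers were added after. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean for each of the 6 groups and an additive term for the number run, and left 18 residual degrees of freedom. The labels name no batch. The run was inferred from a gap in the title numbers and estimated from WT arrays, which lay in both runs, and its term passed the test for 1362 clusters, 904 of them higher in the second run. P-values were adjusted by Benjamini and Hochberg over all clusters of a comparison, with calls at an adjusted p under 0.05 and no minimum fold. Each estimate is a log2 difference with its standard error from the model. Group means are given with SD.

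Named genes were those with the 8 largest rises and 8 largest falls among called clusters with 1 symbol, leaving out predicted genes, clones, small RNAs and olfactory or vomeronasal receptors. The kinase genes and sort markers were eligible whatever their test. From each list up to 3 called members with the largest change were eligible, or up to 2 with the smallest p where none was called. The text names part of these genes, mostly those whose call held when any 1 array was left out.

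The 35 gene lists, written from general knowledge of iNKT subsets, cell cycle, metabolism, signalling and other thymic cell types, were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over lists within each comparison. Calls were repeated with an estimated correlation and with fry. Members called are counted over all clusters and again adjusted over the list alone. The single dKOMst S3 array was compared with the 3 WT S3 arrays of its run by differences, with the moderated limma test, which takes its spread from the other groups, as an alternative, and list medians were set against 10000 random lists matched on mean expression.

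Comparisons of effects used separate WT arrays for each effect, so that no chance values were shared. Mouse sex was read from Y-linked genes. Mst1KO replicates 3 and 4 of each stage lacked Y-linked signal (means of 4.46 to 4.72) and all other arrays had it (8.02 to 8.94).

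The tests were tried on simulated values for 22206 clusters with the same groups and runs, with 50 clusters changed at each of 4 sizes. At a log2 change of 0.5, 82% were called for the WT stages, 76% for Mst1KO at S1_S2, 56% for Mst1KO at S3 and 28% for dKOMst at S1_S2. At a log2 change of 1 these were 96%, 96%, 94% and 90%, and at 1.5 and 2 all were 100%. Unchanged clusters were called 7, 12, 9 and 13 times. The list moved in the simulation was called each time and 0 of 34 other lists were. The simulated noise was independent between clusters, so this does not show how often lists whose members vary together are called wrongly. Sensitivity to small changes was therefore lower for dKOMst, and the number of arrays limits the precision throughout.

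Alternatives left out the run term, took it as a random block, kept only the groups compared, normalized or centred the arrays again, kept the brighter clusters, weighted the arrays, used a trended and robust variance, required a 1.5-fold change, kept 1 run, kept male arrays, added a sex term and left out each array in turn. Tables were handled with jsonlite 2.0.0, and figures were drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Raw intensity files were not used here.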

Results

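Invariant natural killer T (iNKT) cells are T lymphocytes that recognise lipids presented by CD1d and mature in the thymus through steps defined by CD44 and NK1.1. Genome-wide transcript levels were measured on 25 arrays of iNKT cells sorted from mouse thymus. The cells came from wild-type (WT) mice, from mice lacking the Hippo kinase Mst1 (Mst1KO) and from mice lacking Mst1 and Mst2 (dKOMst). Cells of stages 1 and 2, which lack NK1.1, were hybridised together as S1_S2, and NK1.1-positive stage 3 cells as S3. The groups held 6 WT, 4 Mst1KO and 2 dKOMst arrays of S1_S2 cells, and 7 WT, 5 Mst1KO and 1 dKOMst array of S3 cells. Levels are log2 RMA values, so a difference of 1 is a doubling. The number of arrays limits the precision, and so do levels near the negative controls. The labels do not say that the arrays of a group came from separate animals, so the p-values measure only the spread between these arrays, which may be technical.

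The numbers in the sample titles fell into a first run (16 arrays, with all Mst1KO arrays) and a second run (9 arrays, with all dKOMst arrays). WT arrays were in both runs. The run was therefore a term in the model, and values within a run are given beside the main ones. The first principal component held 34.3% of the variance and separated the stages, from -29.3 to -22.1 in S1_S2 and from 17.2 to 30 in S3. The third (7.46%) separated the Mst1KO arrays (-18.7 to -10.7) from the WT arrays (-0.709 to 15.7), with the dKOMst arrays between -1.6 and 0.902. Replicates within a group correlated at r of 0.981 to 0.9927 across genes.

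The targeted gene was examined first. Stk4, which encodes Mst1, had a mean of 10.46 ± 0.19 (SD, n = 6) in WT S1_S2 and 9.31 ± 0.07 (n = 4) in Mst1KO S1_S2. It averaged 10.28 ± 0.42 (n = 7) in WT S3, 9.74 ± 0.28 (n = 5) in Mst1KO S3 and 9.95 ± 0.46 (n = 2) in dKOMst S1_S2, and the dKOMst S3 array read 10.08. The dKOMst S1_S2 replicates 1 and 2 read 10.27 and 9.63, against 10.18 to 10.74 over all WT S1_S2 arrays and 10.54 to 10.74 over those of their run. Stk4 fell by 0.92 ± 0.16 (SE) on the log2 scale in Mst1KO at S1_S2 (limma adjusted p = 0.0059), with -1.0 within the first run (adjusted p = 0.0054), but with male arrays alone, 2 Mst1KO arrays fewer, the change was -0.88 ± 0.20 (limma adjusted p = 0.15). The differences of -0.35 ± 0.15 in Mst1KO at S3 (limma adjusted p = 0.15) and -0.74 ± 0.20 in dKOMst at S1_S2 (adjusted p = 0.083) did not pass. The position of the Stk4 probes relative to the deleted part is not given in the sources used here, and probes outside the deleted part would check nothing. Stk3, which encodes Mst2, is not named in the probe table used here. CD44 and NK1.1 defined the sort, so the change of Cd44 (1.00 ± 0.09) and of Klrb1c, the NK1.1 gene (3.24 ± 0.16), between the WT stages is no finding. Cd24a, whose product was used to exclude immature cells, had means of 4.83 and 5.05 in the WT groups.

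**Figure D1:**
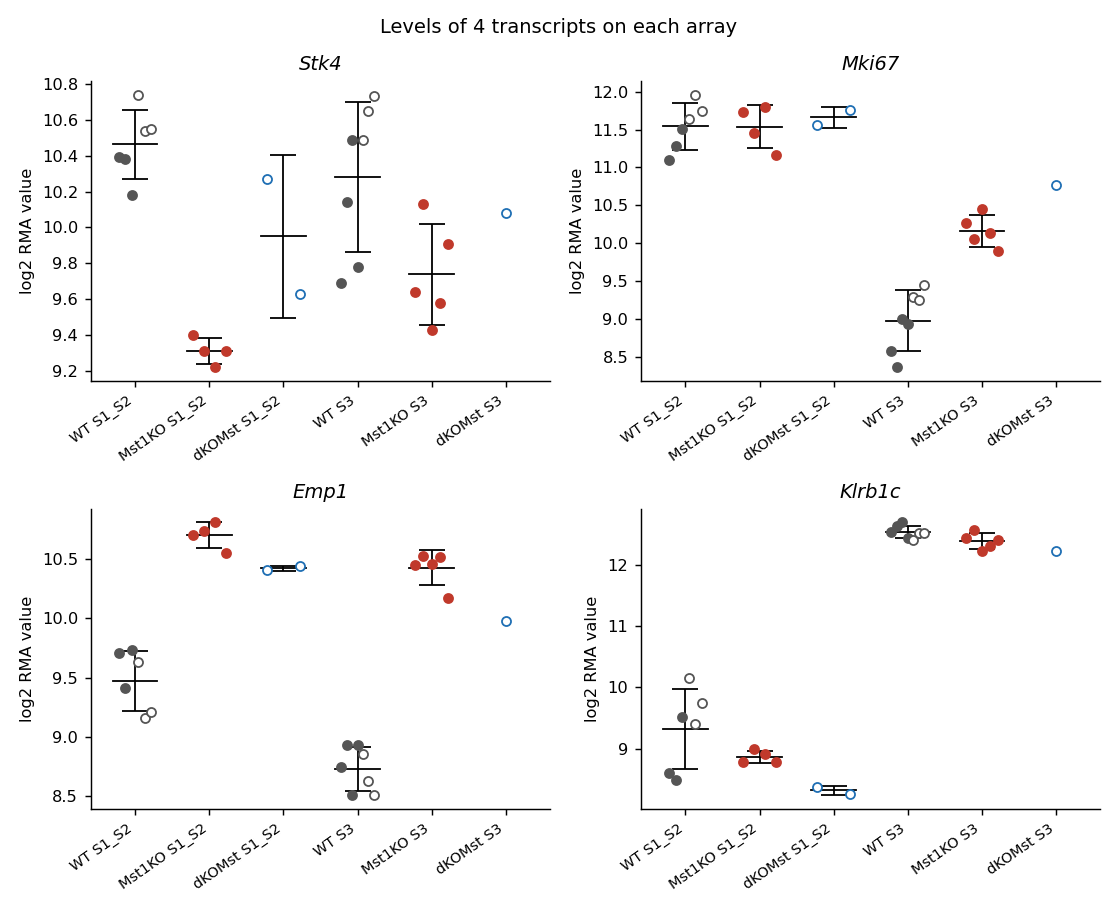
Log2 RMA levels of Stk4, Mki67, Emp1 and Klrb1c on each array, by group, with filled points for the first run, open points for the second, and lines and bars for the group mean ± SD. Stk4 spans 9.22 to 9.40 in Mst1KO S1_S2 against 10.18 to 10.74 in WT S1_S2, while Mki67 averages 10.16 in Mst1KO S3 against 8.98 in WT S3.

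The WT arrays show how the sorted S1_S2 and S3 cells differ. Changes during maturation were not separated from a different mix of iNKT subsets. Genes of natural killer cells and of killing rose from S1_S2 to S3. Klre1, an NK receptor, rose from 6.48 ± 0.50 (SD, n = 6) to 12.14 ± 0.12 (n = 7), a log2 change of 5.64 ± 0.16 (SE). Gzmb, the protease granzyme B, rose by 4.61 ± 0.24, Prf1, the pore former perforin, by 3.30 ± 0.19, and Ifng, interferon gamma, by 3.37 ± 0.23. Over the same step the thymic homing receptor Ccr9 (-4.29 ± 0.16), the interleukin-6 receptor gene Il6ra (-3.67 ± 0.19) and the proliferation marker Mki67 (-2.52 ± 0.12) fell. All of these had limma adjusted p of 8.6e-11 or below and the direction held on each of the 7 S3 arrays against the S1_S2 arrays of its run. At their low end these genes came near the arrays' negative controls, with Klre1 and Ifng above them on 2 of 6 S1_S2 arrays and Ccr9 on 5 of 7 S3 arrays, so the folds are less exact than their errors.

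Of 20 measured NKT1 markers, genes of the interferon-producing subset, all 20 rose between the WT stages (median log2 change 3.04), as did 20 of 21 NK receptors (21 adjusted over the list alone; median 3.24) and 11 of 17 cytotoxic effector genes (11 adjusted over the list alone, where 2 fell; median 1.42). The NKT1 and NK receptor lists both hold Klrb1c, whose rise between the stages the sort fixed in each genotype. Examples of the other members were the NKG2A gene Klrc1 at 4.75 ± 0.41, its partner Klrd1 at 4.21 ± 0.34, the granzyme Gzma at 4.00 ± 0.20 and the chemokine Xcl1 at 3.13 ± 0.12. Klrc1 lay above the negative controls on 1 of 6 S1_S2 arrays (replicate 3, at 8.49) and Gzma on 4, so these folds are inexact. All 26 G2 and M phase genes fell (median -1.74), with the mitotic kinase Cdk1 at -2.67 ± 0.19 (above the negative controls on 5 of 7 S3 arrays), and 22 of 26 G1 to S phase genes fell while 1 rose (23 and 1 adjusted over the list alone; median -1.01), with the transcription factor E2f2 at -2.54 ± 0.15. Of 14 NKT2 markers, genes of the interleukin-4-producing subset, 12 fell and 2 rose (12 and 2 adjusted over the list alone; median -1.07), including the interleukin-25 receptor gene Il17rb at -2.76 ± 0.24 and Plac8 at -2.86 ± 0.27. Of 17 early iNKT and immature thymocyte genes, 13 fell (13 adjusted over the list alone; median -0.51), among them Themis, a selection factor, at -2.32 ± 0.15. These 7 lists passed limma camera with a preset correlation (adjusted p of 1.4e-10 or below) and with an estimated correlation, where the highest adjusted p was 0.0071.

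Other cells' markers moved with the stage as well. Of 8 NK cell markers 5 rose (5 adjusted over the list alone; median 0.95), with the signalling adaptors Fcer1g at 3.12 ± 0.15 (above the negative controls on 4 of 6 S1_S2 arrays) and Tyrobp at 1.86 ± 0.10, and of 18 myeloid and dendritic cell markers 9 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.42), with the Fc receptor Fcgr3 at 2.22 ± 0.22. Both passed camera (adjusted p = 9.8e-08 and 3.1e-06; with an estimated correlation, 0.00011 and 0.0038). NKT17 markers, genes of the interleukin-17-producing subset, had 5 of 18 members lower (5 adjusted over the list alone; median -0.44, adjusted p = 0.0018), but adjusted p = 0.23 with an estimated correlation, and within the runs the medians were -0.18 (adjusted p = 0.082) and -0.79 (7e-08). Over all genes, 1817 transcript clusters rose and 1943 fell at S3 of 22206 tested, 257 and 311 of them at least 2-fold. Called clusters numbered 965 with first-run arrays alone and 1718 with second-run arrays alone. Of 35 gene lists, 22 passed camera with the preset and 13 with the estimated correlation.

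Cells without Mst1 were compared with WT cells at S1_S2 to find how they differ among cells that lack NK1.1. The transcription factor genes Fos and Jun, which turn on within minutes of a stimulus, rose by 1.40 ± 0.20 and 1.49 ± 0.22, and Cd69, an activation marker that retains cells in tissue, rose from 9.97 ± 0.34 (SD, n = 6) to 11.14 ± 0.05 (n = 4), by 1.05 ± 0.16. Ly6c2, a surface protein of memory-like T cells, rose by 1.15 ± 0.09 and the adhesion molecule gene Jaml by 1.47 ± 0.14. The flippase gene Atp8a2 (-1.75 ± 0.16), the macrophage growth factor gene Csf1 (-1.96 ± 0.27) and the cytokine gene Il4 (-0.78 ± 0.13) fell.

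Among T cell receptor signal and immediate early genes, 5 of 24 rose (9 rose and 3 fell adjusted over the list alone; median 0.16, camera adjusted p = 3.5e-06), but the list had adjusted p = 0.11 with an estimated correlation. Fosb, another such gene, rose by 1.79 ± 0.28. Of 18 NKT17 markers only Il18r1, the interleukin-18 receptor gene, passed over all genes (0.46 ± 0.10), while 8 rose adjusted over the list alone (median 0.65, adjusted p = 8.3e-11; adjusted p = 0.071 with an estimated correlation). The call of Il18r1 was lost without WT replicates 1 and 2 (adjusted p of 0.062 and 0.1) and without Mst1KO replicates 1 to 4 (0.069, 0.071, 0.087 and 0.1). Within the first run the NKT17 median was 0.84 (limma camera adjusted p = 1.2e-23) and 7 members rose. Cd163l1, a gamma-delta T cell marker, rose by 0.77 ± 0.14 beside them, with limma adjusted p = 0.073 within the first run, while Sox13 of the same list of 4 fell by 0.67 ± 0.14 (limma adjusted p = 0.027; 0.1 without WT replicate 2, 0.069 and 0.12 without Mst1KO replicates 2 and 3; list median -0.05). Quiescence-associated genes had a median of 0.19 (adjusted p = 4.5e-05; 0 of 23 passed in limma over all genes and 2 rose adjusted over the list alone), and adhesion and egress genes a median of 0.13 (adjusted p = 0.0012; Cd69 alone passed over all genes, and 4 rose over the list alone). These 2 lists were the only ones of the 12 called here that also passed with an estimated correlation (adjusted p = 0.02 for each).

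Of NKT2 markers, Il4 and the folate receptor-like gene Izumo1r (-0.63 ± 0.09) fell (adjusted over the list alone, 4 fell and 1 rose; median -0.16, limma camera adjusted p = 0.0097). The list had adjusted p = 0.32 with an estimated correlation and 0.079 without WT S1_S2 replicate 2. NKT1 markers were called as higher, with a median of only 0.04 (limma camera adjusted p = 0.0018; 0.1 without WT S1_S2 replicate 1). Of these Ly6c2 and Ifng passed limma. Ifng rose by 1.48 ± 0.28 (limma adjusted p = 0.012) from a WT mean of 6.26 ± 0.59 (SD), near the negative controls. Hippo pathway components did not move as a list (median 0.02, mean -0.00, limma camera adjusted p = 0.87), and of 27 only Stk4 fell. YAP and TAZ target genes, which the Hippo pathway restrains in other tissues, had a median of 0.06 (limma camera adjusted p = 0.17), and of 22 only Dock5 (0.92 ± 0.21) and Gadd45b (0.69 ± 0.16) rose. Limma adjusted p of Dock5 was 0.048, and 0.059, 0.16, 0.07 and 0.077 without WT replicates 1, 2, 4 and 5 and 0.083, 0.2, 0.091 and 0.12 without Mst1KO replicates 1 to 4. That of Gadd45b was 0.039, and 0.14, 0.11, 0.057 and 0.062 without WT replicates 1 to 4 and 0.13, 0.11 and 0.18 without Mst1KO replicates 2 to 4. No member of the B cell, myeloid, double-positive thymocyte, thymic epithelium, erythroid, regulatory T cell or NK cell marker lists passed limma over all genes.

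Altogether 73 clusters rose and 43 fell in Mst1KO at S1_S2 (62.9% higher), 20 and 16 at least 2-fold, and the limma adjusted p of the genes named as rising or falling there ranged from 7.9e-08 for Ly6c2 to 0.048 for Dock5. Within the first run 48 clusters were called and Csf1, Il4 and Fosb had adjusted p of 0.065, 0.054 and 0.075. The total of 116 dropped to 68 and 77 without WT S1_S2 replicates 1 and 2, and to 67, 66, 75 and 71 without Mst1KO S1_S2 replicates 1 to 4. Male arrays alone, with 2 Mst1KO arrays left, gave 23, and Cd69 and Fosb then had limma adjusted p = 0.083.

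NK1.1-positive cells without Mst1 were compared with WT cells at S3. Genes of cell division were higher. Mki67 rose from 8.98 ± 0.40 (SD, n = 7) to 10.16 ± 0.21 (n = 5), a fitted log2 change of 1.42 ± 0.13, Cdk1 rose by 1.34 ± 0.21 and the cell cycle transcription factor gene E2f8 by 1.75 ± 0.24 (Cdk1 and E2f8 lay above the negative controls on 5 and 4 of 7 WT arrays). The integrin gene Itga4 rose by 1.54 ± 0.16, S1pr1, the receptor that guides thymic egress, by 1.13 ± 0.12 and the membrane protein gene Emp1 by 1.61 ± 0.11. Gzma (-2.08 ± 0.23), Atp8a2 (-2.15 ± 0.14), the RNA sensor gene Tlr7 (-2.09 ± 0.29) and Bcl2l11, which encodes the death inducer Bim (-0.89 ± 0.12), fell. Each of the 5 Mst1KO arrays lay beyond all first-run WT S3 arrays for these genes.

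Of 26 G2 and M phase genes 13 rose (18 adjusted over the list alone; median 0.68, limma camera adjusted p = 4.6e-17), and of 26 G1 to S phase genes 14 rose (19 adjusted over the list alone; median 0.41, adjusted p = 8.3e-17). Both passed with an estimated correlation (adjusted p = 0.032 and 0.0037), and within the first run the medians were 0.67 and 0.49. E2f2 rose by 1.1 ± 0.17 and Stmn1, a microtubule regulator gene, by 1.00 ± 0.14. The test of the genotype effect at S3 minus that at S1_S2 gave a median of 0.52 for G1 to S phase genes (adjusted p = 1.7e-16; 0.0037 with an estimated correlation), although 0 of the 26 passed in limma over all genes and 16 did adjusted over the list alone. For G2 and M phase genes it gave 0.58 (adjusted p = 2.4e-13; adjusted p = 0.09 with an estimated correlation), with 1 member past over all genes, Mki67 at 1.14 ± 0.19 (adjusted p = 0.0063; 0.071 with no run term), and 9 over the list alone.

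Adhesion and egress genes had 5 of 18 members higher and 1 lower (7 and 2 adjusted over the list alone; median 0.16, limma camera adjusted p = 0.0021), with Cd69 at 0.81 ± 0.15 beside Itga4 and S1pr1. Amino acid transport and integrated stress response genes had 3 of 22 higher and 1 lower (8 and 1 adjusted over the list alone; median 0.19, limma camera adjusted p = 0.0023), with the tRNA synthetase gene Cars at 0.89 ± 0.16. Inhibitory receptors had 3 of 11 lower (6 adjusted over the list alone; median -0.43, limma camera adjusted p = 0.0043), with Cd160 at -0.68 ± 0.12. With an estimated correlation these 3 lists had adjusted p of 0.022, 0.029 and 0.029, and with the 2 cell cycle lists they were the 5 of 13 called lists that passed that way.

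Immediate early genes had 8 of 24 members higher and 3 lower (10 and 4 adjusted over the list alone; median 0.14, adjusted p = 0.0023), with Fosb at 1.44 ± 0.25 and Jun at 1.14 ± 0.20, but adjusted p = 0.3 with an estimated correlation. Heat shock and stress genes had 1 of 10 members higher (2 adjusted over the list alone; median 0.18, limma camera adjusted p = 0.012; 0.084 without Mst1KO S3 replicate 1), but adjusted p = 0.32 with an estimated correlation. That member, the chaperone gene Hspa1a, rose by 1.07 ± 0.29 (limma adjusted p = 0.031; 0.06 and 0.066 without WT S3 replicates 1 and 2, 0.074, 0.054 and 0.076 without Mst1KO S3 replicates 1, 3 and 4). NKT17 markers had 4 of 18 higher (7 higher and 1 lower adjusted over the list alone; median 0.44, adjusted p = 7.9e-05), including the integrin gene Itgb3 at 0.82 ± 0.18, but adjusted p = 0.25 with an estimated correlation. The list mean stood apart on Mst1KO S3 replicate 4 (9.38 against 8.97 to 9.03), and without that array the median was 0.39 (limma camera adjusted p = 0.00068). Cd163l1 rose beside them by 0.82 ± 0.12. NKT1 markers (2 higher and 2 lower of 20, also adjusted over the list alone; median 0.02, mean -0.04, limma camera adjusted p = 0.66) and NK receptors (2 higher and 2 lower of 21, 2 and 3 adjusted over the list alone; median 0.05, adjusted p = 0.44) did not move as lists. Cytotoxic effector genes had 1 of 17 higher, Gzmc at 1.25 ± 0.19, and 3 lower, Gzma, Tnfsf10 (-0.66 ± 0.15) and Serpinb9 (-0.61 ± 0.14; 1 higher and 4 lower adjusted over the list alone; median -0.04, limma camera adjusted p = 0.29). On first-run arrays alone the mean of this list was 9.56 in Mst1KO and 9.73 in WT (exact permutation p = 0.00794, the smallest that 126 splits allow), while limma camera gave adjusted p = 0.31. Hippo pathway components (median -0.02, mean 0.04, adjusted p = 0.29) and YAP and TAZ target genes (median -0.04, mean 0.03, adjusted p = 0.73) did not move as lists.

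Single members of such lists did pass in Mst1KO at S3. The Hippo kinase gene Stk38 rose by 0.47 ± 0.10 (limma adjusted p = 0.0076). Taok1, another kinase gene, rose by 0.37 ± 0.11 (limma adjusted p = 0.049; 0.12, 0.12, 0.072 and 0.06 without WT S3 replicates 2 to 5, 0.074, 0.13, 0.077 and 0.07 without Mst1KO S3 replicates 1, 2, 3 and 5). The Mst1 partner gene Rassf5 fell by 0.28 ± 0.08 (limma adjusted p = 0.04; 0.055, 0.069, 0.098 and 0.051 without WT S3 replicates 1, 2, 3 and 6, 0.051, 0.078, 0.089 and 0.072 without Mst1KO S3 replicates 1, 2, 4 and 5). Dock5 rose by 0.74 ± 0.19 (limma adjusted p = 0.023; 0.058 without WT S3 replicate 2 and 0.057 without Mst1KO S3 replicate 5). Of NK cell markers, Tyrobp (0.74 ± 0.11, limma adjusted p = 0.00049) and the transcription factor gene Eomes (0.67 ± 0.14, 0.0076) rose, the latter from 1 of 7 WT to 3 of 5 Mst1KO arrays above the negative controls. The NK receptor gene Ncr1 was lower, above the negative controls on 4 of 7 WT and 0 of 5 Mst1KO arrays, so that its log2 difference was at least 0.02 (limma adjusted p = 0.044; 0.1, 0.11, 0.068 and 0.056 without WT S3 replicates 1, 2, 4 and 7, 0.12, 0.085 and 0.072 without Mst1KO S3 replicates 2, 4 and 5). The regulatory T cell marker Ikzf4 fell by 0.45 ± 0.10 (limma adjusted p = 0.0075). Cd24a, whose product the sort excluded, read 5.05 ± 0.19 in WT S3 and 5.47 ± 0.36 in Mst1KO S3 (SD, n = 7 and 5), above the negative controls on 0 arrays, so no fold is given (limma adjusted p = 0.042; 0.073, 0.075 and 0.052 without WT S3 replicates 3, 4 and 7, 0.091, 0.09 and 0.11 without Mst1KO S3 replicates 2 to 4). The other sort marker genes, Cd44 and Klrb1c, differed by 0.13 and 0.01 (limma adjusted p = 0.44 and 0.97). None of the B cell, myeloid, thymic epithelium or erythroid markers passed limma. Of the double-positive thymocyte markers Cd8b1 rose by 0.73 ± 0.18 (adjusted p of 0.052 without WT S3 replicate 3 and 0.059 without Mst1KO S3 replicate 5).

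**Figure D2:**
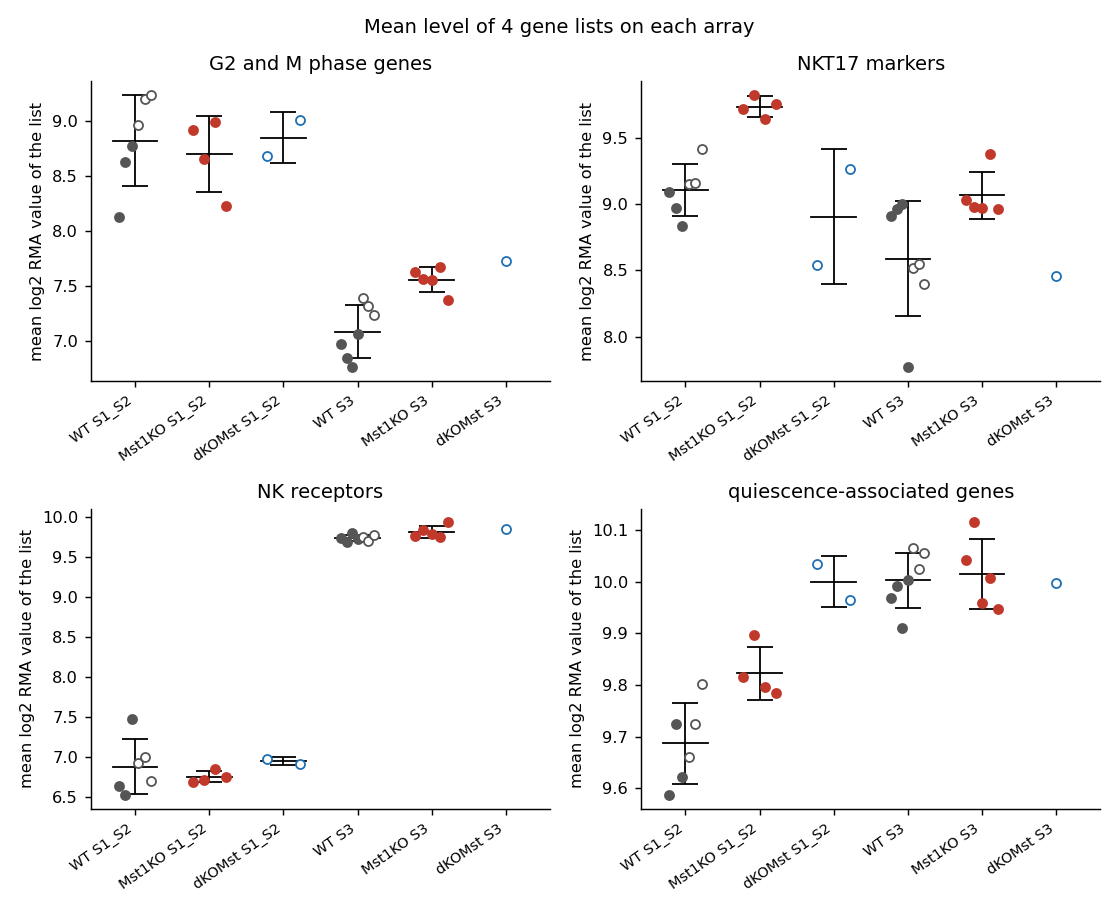
Mean log2 level of the members of 4 gene lists on each array, by group, with filled points for the first run, open points for the second, and lines and bars for the group mean ± SD. G2 and M phase genes and NK receptors separate the stages in opposite directions, and the Mst1KO S3 arrays lie above the WT S3 arrays of the first run for G2 and M phase genes.

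Over all genes 829 clusters rose and 586 fell in Mst1KO at S3, 81 and 24 of them at least 2-fold, and the limma adjusted p of the genes named there as rising or falling ranged from 3.6e-09 for Emp1 and Atp8a2 to 0.049 for Taok1. Higher calls made up 58.6%, and 73% after each array was centred on its median. The total of 1415 was 336 with first-run arrays alone, 871 without Mst1KO S3 replicate 2 and 783 without replicate 5.

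The step from S1_S2 to S3 was measured in Mst1KO cells as well. Klre1 rose by 5.50 ± 0.20, Gzmb by 4.24 ± 0.29 and Ifng by 2.96 ± 0.27, while Ccr9 (-2.64 ± 0.20), Il6ra (-2.73 ± 0.22) and Cdk1 (-1.62 ± 0.23) fell. Of NKT1 markers 19 of 20 rose (20 adjusted over the list alone; median 2.27), of NK receptors 17 of 21 (19; median 3.52) and of cytotoxic effector genes 10 of 17 (10; median 1.36). Of G2 and M phase genes 22 of 26 fell (26 adjusted over the list alone; median -1.17, camera adjusted p = 5.5e-24; 0.0066 with an estimated correlation), and of G1 to S phase genes 16 fell and 1 rose (18 and 1; median -0.58, adjusted p = 1.1e-09; 0.0081 with an estimated correlation). Of the clusters called in each genotype, 925 rose in both (101 for independent lists), 683 fell in both (89.8) and 2 moved in opposite directions. In all 1240 clusters rose and 1026 fell (54.7% higher, 68.1% after centring). Stk4 differed by 0.43 ± 0.16 (limma adjusted p = 0.088), and the other named genes had adjusted p of 2.1e-05 or below.

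The genotype effect differed between the stages for 35 clusters, 20 with a higher and 15 with a lower value at S3 (57.1% higher, 72.7% after centring). Ccr9 was lower than WT in Mst1KO at S1_S2 by the group means (10.18 against 11.03) and higher at S3 (7.54 against 6.72), a difference of effects of 1.64 ± 0.25 (limma adjusted p = 0.0058). Gzma had a difference of -2.11 ± 0.31 (limma adjusted p = 0.0058), the cytoskeletal adaptor gene Pdlim1 of 1.24 ± 0.21 (0.01), and Ly6c2 and its relative Ly6c1 of -0.87 ± 0.11 (0.00089) and -0.81 ± 0.12 (0.0055). The total rose to 61 without WT S1_S2 replicate 3. It dropped to 23 and 20 without WT S1_S2 replicates 2 and 5, to 22 without WT S3 replicate 1, to 21, 14, 20 and 20 without Mst1KO S1_S2 replicates 1 to 4, and to 15, 23, 18 and 17 without Mst1KO S3 replicates 2 to 5. Male arrays alone gave 0 by limma, with 1504 clusters at an unadjusted p under 0.05.

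Whether the Mst1KO effect at S3 fell on genes of the stage step was asked with separate WT arrays. Among second-run WT arrays 24 of 26 G2 and M phase genes and 20 of 26 G1 to S phase genes were called lower at S3. The sets were not tested without cell cycle genes. A rise of the clusters lower at S3 may therefore partly restate the rise of those genes. Clusters at least 2-fold lower at S3 in second-run WT arrays (361) had a median change of 0.34 in Mst1KO at S3 within the first run, against -0.05 for all clusters (limma camera p = 8.1e-24; 0.00017 with an estimated correlation), 285 of them (78.9%) were above 0, and the 266 clusters higher at S3 had a median of -0.05 (p = 0.75). In dKOMst at S1_S2 within the second run, sets chosen from first-run WT arrays had medians of -0.13 for the 256 lower clusters (limma camera p = 0.00029; 0.15 with an estimated correlation) and 0.10 for the 229 higher clusters (p = 0.033; 0.3 without dKOMst replicate 2).

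At S1_S2 the 2 dKOMst arrays were compared with WT. Fcer1g, a signalling adaptor gene of NK and myeloid cells, rose from 6.37 ± 0.44 (SD, n = 6) to 8.47 ± 0.16 (n = 2), a fitted log2 change of 2.06 ± 0.24, and the lectin receptor gene Klra7 rose by 1.69 ± 0.22. The lectin receptor gene Klrb1 and the granzyme gene Gzmc, above the negative controls on 0 of 6 WT arrays, rose by at least 0.83 and 0.88. Ly6c2 rose by 1.45 ± 0.11. The potassium channel gene Kcnn2, above the negative controls on 0 of 2 dKOMst arrays, was lower by at least 2.05, and Csf1 (-2.36 ± 0.33), Samd3 (-2.18 ± 0.23) and Atp8a2 (-1.78 ± 0.20) fell. Limma adjusted p of these genes lay between 4.7e-08 for Ly6c2 and 0.0013 for Gzmc, and both dKOMst arrays lay beyond all second-run WT arrays. Fcer1g was above the negative controls on 4 of 6 WT arrays and Samd3 on 1 of 2 dKOMst arrays. NK receptors did not move as a list (2 of 21 higher and 1 lower, 4 and 2 adjusted over the list alone; median 0.01, limma camera adjusted p = 0.83).

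Of 8 NK cell markers 3 rose in dKOMst at S1_S2 (4 rose and 1 fell adjusted over the list alone; median 0.44, camera adjusted p = 0.00056; 0.018 with an estimated correlation), but over the brighter clusters the list had adjusted p = 0.15. Beside them the NK1.1 gene Klrb1c, which the sort selected against, differed by -1.18 ± 0.25 (limma adjusted p = 0.02; 0.21 and 0.17 without dKOMst replicates 1 and 2, 0.056 and 0.058 without WT replicates 4 and 6). Markers of other cells moved as well. Itgam, which is on the NK cell and the myeloid list, rose by 0.93 ± 0.18 (limma adjusted p = 0.008; 0.29 without dKOMst replicate 1). The lysozyme gene Lyz2, above the negative controls on 2 of 6 WT arrays, rose by 0.70 ± 0.16 (limma adjusted p = 0.037; 0.051, 0.075 and 0.064 without WT replicates 1, 4 and 6, 0.23 and 0.26 without dKOMst replicates 1 and 2). Ctsl, a protease gene on the thymic epithelium list, rose by 0.73 ± 0.15 (limma adjusted p = 0.017; 0.051 without WT replicate 6 and 0.45 without dKOMst replicate 1). Myeloid and dendritic cell markers had 2 of 18 higher (2 adjusted over the list alone; median 0.21, limma camera adjusted p = 0.023; 0.11 without dKOMst replicate 1) but adjusted p = 0.17 with an estimated correlation. Erythroid markers had 0 of 4 past limma, also adjusted over the list alone (median 0.24, limma camera adjusted p = 0.023; 0.052 and 0.051 without WT replicates 4 and 6, 0.21 without dKOMst replicate 2), but adjusted p = 0.17 with an estimated correlation.

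In dKOMst at S1_S2 quiescence-associated genes had 5 of 23 members higher (11 higher and 2 lower adjusted over the list alone; median 0.28, adjusted p = 3.7e-05; 0.018 with an estimated correlation), including S1pr1 at 0.97 ± 0.17 (adjusted p = 0.0026; 0.2 without dKOMst replicate 1). Ribosomal protein genes had 1 of 29 members lower over all genes and 15 adjusted over the list alone (median -0.18, adjusted p = 9.1e-18; 0.045 with an estimated correlation). These 3 of 11 called lists were those that passed with an estimated correlation.

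Actin and Mst1 migration machinery had 3 of 20 members higher (7 adjusted over the list alone; median 0.16, adjusted p = 9.6e-07) but adjusted p = 0.07 with an estimated correlation. Among NF-kB target genes the survival genes Bcl2a1a, Bcl2a1b and Bcl2a1d fell (-0.68 ± 0.13, -0.59 ± 0.08 and -0.60 ± 0.09; 4 members fell and 1 rose adjusted over the list alone; median -0.05, adjusted p = 0.0038), but the list had adjusted p = 0.1 with an estimated correlation, and without dKOMst replicate 1 the 3 genes had adjusted p of 0.23, 0.054 and 0.16. These near-identical genes share sequence, so their signals may not be separate. Il4 fell by 0.90 ± 0.15 (limma adjusted p = 0.0026; 0.12 without dKOMst replicate 2) and Itga4 rose by 1.43 ± 0.22 (adjusted p = 0.00085; 0.057 without replicate 1). NKT17 markers did not move as a list (median -0.10, limma camera adjusted p = 0.18), although within the second run their median was -0.28 (adjusted p = 0.029). Over all genes 123 clusters rose and 82 fell, 47 and 32 at least 2-fold. The total of 205 was 100 with second-run arrays alone, 33 without dKOMst replicate 1 and 107 without replicate 2, where the remaining array was assumed to vary like the other groups.

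**Figure D3:**
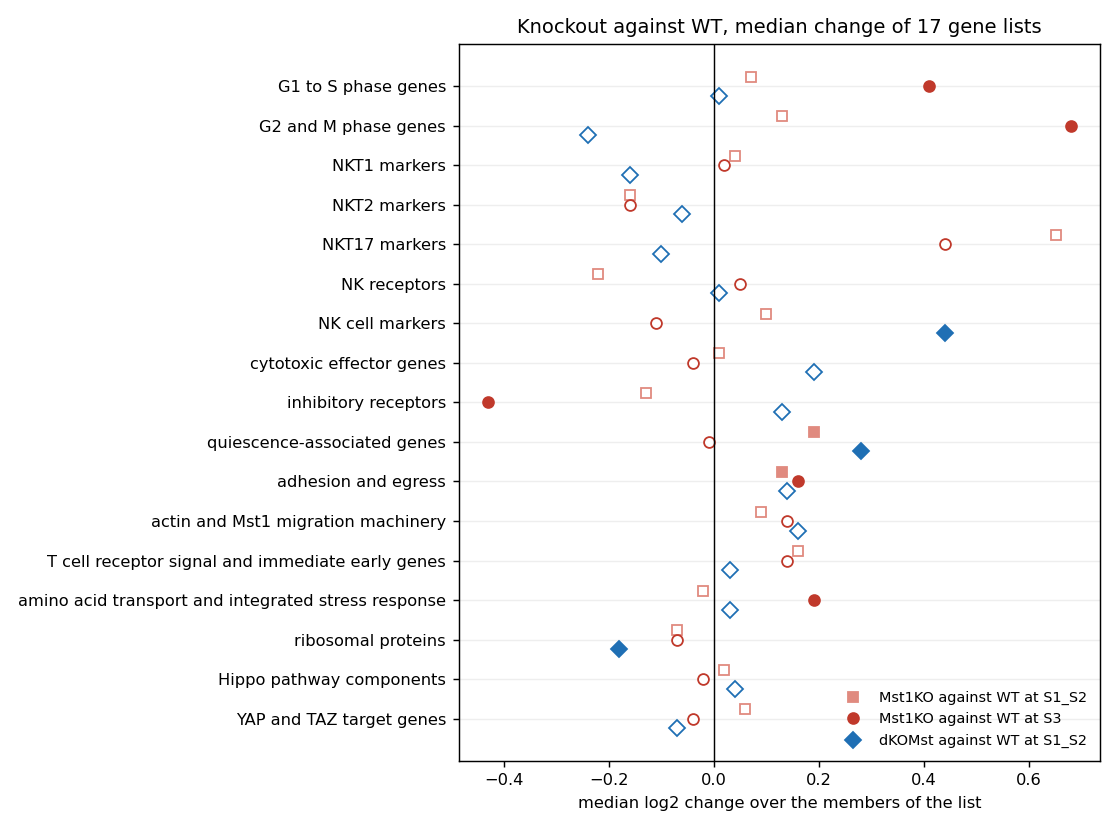
Median log2 change over the members of 17 gene lists for Mst1KO against WT at S1_S2, Mst1KO against WT at S3 and dKOMst against WT at S1_S2, with filled points for lists past camera with the preset and the estimated correlation. G2 and M phase genes have a median of 0.68 in Mst1KO at S3.

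The kinase knockouts were set side by side at S1_S2 with separate WT arrays, Mst1KO against the 3 first-run arrays and dKOMst against the 3 second-run arrays. Ly6c2 was higher by 1.20 in Mst1KO and 1.40 in dKOMst, Csf1 lower by -1.91 and -2.41 and Atp8a2 lower by -1.77 and -1.75 in these fits. Fos differed by 1.51 in Mst1KO and -0.01 in dKOMst, Fcer1g by 0.25 and 1.91, and Tlr7 by -0.61 and -2.53. Across all genes, which are not independent replicates, the changes correlated at r = 0.132 and rho = 0.0797. The calls shared 6 higher clusters of 39 and 66 (0.116 for independent lists) and 1 lower cluster of 9 and 34 (0.0138).

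Between the knockouts themselves at S1_S2, 26 clusters were higher and 12 lower in dKOMst than in Mst1KO. Gcsam, a signalling protein gene of germinal centre lymphocytes, was higher by 2.16 ± 0.25 (limma adjusted p = 0.00018) and the troponin gene Tnni1 by 2.03 ± 0.21 (3.3e-05). Both were dim, with means over all arrays of 6.81 and 6.62 near the negative controls, so these sizes are less exact than their errors. Fcer1g, above the negative controls on 1 of 4 Mst1KO arrays, was higher by 1.96 ± 0.28 (0.0017), Samd3 lower by -1.87 ± 0.27 (0.0017) and Bcl2a1b lower by -0.63 ± 0.10 (0.0036), but without dKOMst replicate 1 these 3 had adjusted p of 0.098, 0.12 and 0.15. NKT17 markers had a median of -0.80 (camera adjusted p = 6e-09; 0 of 18 passed in limma over all genes, 9 were lower adjusted over the list alone) but adjusted p = 0.097 with an estimated correlation, and none of the 13 lists called passed that way. The knockouts lay in different runs and met only through the WT arrays, and the total of 38 was 195 with no run term and 4 without dKOMst replicate 1.

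**Figure D4:**
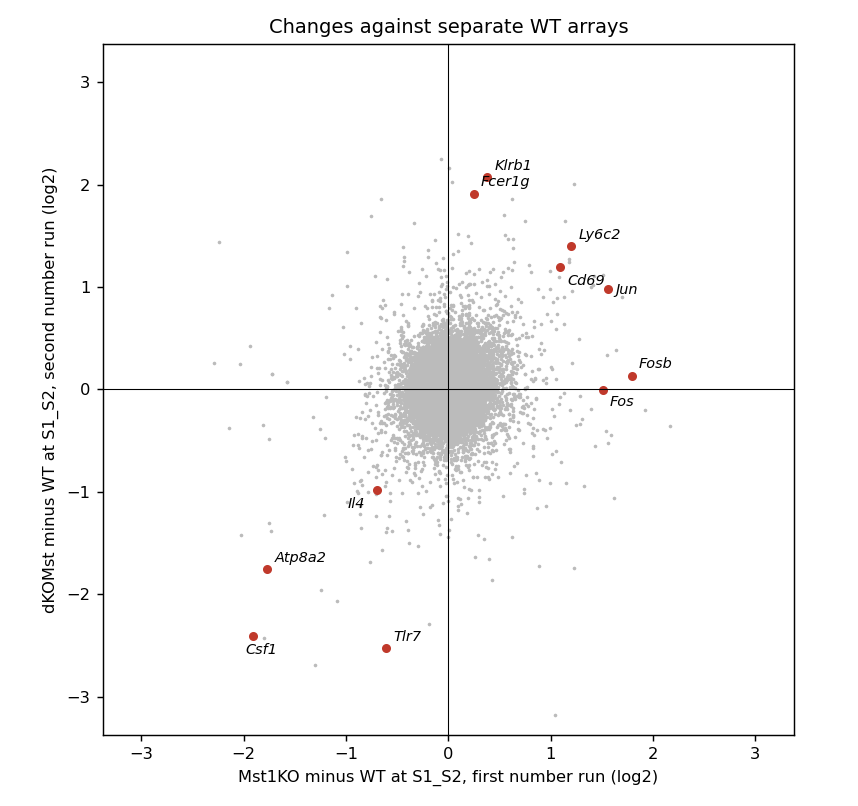
Log2 change of each transcript cluster at S1_S2 for Mst1KO against first-run WT arrays (horizontal) and dKOMst against second-run WT arrays (vertical), with 11 genes named. Ly6c2, Csf1 and Atp8a2 change the same way on both axes, while Fos lies at 1.51 and -0.01 and Fcer1g at 0.25 and 1.91.

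The single dKOMst S3 array has no replicate, so its differences from the 3 second-run WT S3 arrays have no replicate check. Itga4 read 11.46 against 9.60 ± 0.17 (SD, n = 3), Mki67 10.77 against 9.33 ± 0.11, S1pr1 9.91 against 8.43 ± 0.14 and Emp1 9.98 against 8.66 ± 0.18. The TGF-beta co-receptor gene Tgfbr3 read 8.16 against 9.94 ± 0.19. The lamin A gene Lmna differed by 1.45, and the protease gene Ctse read 11.59 against 9.56 ± 0.37 and the carboxypeptidase gene Cpe 6.81 against 9.08 ± 0.77. At least 2-fold differences numbered 97 higher and 107 lower clusters, against 93 to 177 in total when each of the 3 WT arrays was set against the other 2.

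Of 26 G2 and M phase genes 22 were higher on this array than the WT mean (median 0.35, the 100th percentile of 10000 random lists matched on mean expression). Oxidative phosphorylation genes were higher in 43 of 48 members (median 0.11, 100th percentile), and NK cell markers had a median of 0.41 (100th percentile). Quiescence-associated genes had a median of -0.20 (percentile 0.07), Hippo pathway components of -0.14 (0.33) and myeloid and dendritic cell markers of -0.16 (0.43). The random lists hold genes drawn at random, and no single WT array was put through this test. The percentiles therefore cannot show whether this array departs from WT. The array's list means lay above all WT S3 arrays for G2 and M phase, oxidative phosphorylation and NK cell marker genes. They lay below them for the Hippo and myeloid lists, and within their range for quiescence-associated genes. Of the 336 clusters called for Mst1KO at S3 in the first run, with other WT arrays, 200 of the 233 higher ones were higher here and 79 of the 103 lower ones were lower, 83% in all against 53.5% of all clusters.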

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

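The tests of mouse sex, number run, single arrays, carried-over cells, a larger share of NKT17-type cells and levels against the negative controls were chosen only after the results were seen, while those of handling and of other splits of the arrays were planned.

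Cell cycle genes were higher in Mst1KO at S3, with Mki67 at 1.42 ± 0.13 and a median of 0.68 for 26 G2 and M phase genes, 25 of them positive. If S1_S2 cells had been carried over into the S3 sort, 22 G2 and M phase genes would need a share of 21.9% (19.1 to 25.5). Another 13 early iNKT and NKT2 genes gave a median of 6.93% (95% interval -4.94 to 12.4), with single genes from -118 to 30.7% (SD 47.7). Without Pdcd1 and Il4, the lowest, the gap between the medians was 13.2 and the SD 14.2. The 13 genes include Stmn1 (28.5%), named above beside the cell cycle genes, so they are not free of proliferation. No high gene was left out in turn, and the outcome may depend on which genes are kept. The intervals do not overlap, but the gap is within the SD, a limit set only after that was seen, so carried-over cells and a change in proliferation of mature cells cannot be told apart. WT S3 arrays themselves differed between the runs, with Mki67 at 8.72 ± 0.30 (SD, n = 4) in the first and 9.33 ± 0.11 (n = 3) in the second. Without the female arrays the G2 and M phase median was 0.62 and with first-run arrays alone 0.67 (camera adjusted p = 1.8e-15 and 1.5e-15 at the preset correlation). Neither mouse sex nor the number run therefore accounts for the rise of this list.

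NKT17 markers were higher in Mst1KO at S1_S2, with a median of 0.65 and 17 of 18 members positive (camera adjusted p = 8.3e-11 at the preset correlation, but adjusted p = 0.071 with an estimated correlation). A larger share of NKT17-type cells in the sort is a possible explanation. Members rose and fell together between arrays of a group, pooled over all groups (mean residual correlation 0.29, against 0.05 at the 95th percentile of matched random lists). Genes of 1 subset may vary together for either reason, so the correlation does not favour a larger share. The list mean varied least in Mst1KO S1_S2 (SD 0.08, against 0.18 to 0.51 in the other replicated groups). Without the female arrays the median was 0.61 (camera adjusted p = 8.7e-09). With any 1 array left out the median stayed between 0.51 and 0.72 and the highest camera adjusted p at the preset correlation was 1.7e-07. The data cannot tell a larger share from higher expression per cell.

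Immediate early genes in Mst1KO at S1_S2 had a median of 0.16, with Fos at 1.40 ± 0.20 and 17 of 24 members positive (camera adjusted p = 3.5e-06 at the preset correlation, but adjusted p = 0.11 with an estimated correlation). Handling of the cells before lysis may contribute, since the list followed the heat shock genes across 24 arrays within groups (r = 0.41, permutation p = 0.046, 100000 permutations). That link is weak, with rho = 0.38 (permutation p = 0.066) and r = 0.28 without the 2 farthest arrays. Heat shock genes themselves had a median of 0.20 in this comparison (camera adjusted p = 0.0032, but adjusted p = 0.28 with an estimated correlation and 0.058 without Mst1KO replicate 1). Without the female arrays the immediate early median was 0.14 against 0.16 (camera adjusted p = 3.7e-05).

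Other splits of the same arrays called fewer clusters than the real one, which was 1 of 100 splits with as many calls each time. The real and the highest other counts were 3760 and 1024 for the WT stages, 116 and 33 for Mst1KO at S1_S2, 1415 and 102 for Mst1KO at S3, 2266 and 1177 for the Mst1KO stages, and 35 and 22 for the difference of the Mst1KO effect between stages. The splits left the real differences in the values, where they widen the spread of a shuffled fit, and moved labels across runs. A low count in other splits is therefore a weak check. For the difference between stages the splits also broke up the genotype effect itself, so they do not test that difference alone. No splits were made for dKOMst, with 2 arrays.

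Of 476 values tested for an array far from the others of its group, 30 stood apart, with 23.8 expected by chance, and their gap as a fraction of the group's range follows. On WT S1_S2 replicate 3 these were Klrc3 at 0.85 (7.52 against 4.63 to 5.07), Klrc1 at 0.643 (8.49 against 4.50 to 5.92), Ccr8 at 0.636, Akap6 at 0.701, Ccr6 at 0.669, Ptprb at 0.692, Stc2 at 0.723, gamma-delta T cell markers at 0.819 and ribosomal proteins at 0.748. On Mst1KO S3 replicate 5 they were Csf1 at 0.779, Emp1 at 0.792, Fosb at 0.775, Klf4 at 0.78 and amino acid and stress response genes at 0.751. On Mst1KO S3 replicate 4 they were Ccr6 at 0.827, Irak3 at 0.797 and NKT17 markers at 0.84. On WT S3 replicate 4, which also lay apart on the fourth principal component (-31.8), they were Fos at 0.591, Ifng at 0.615 and Jun at 0.639. On Mst1KO S3 replicate 2 they were Samd3 at 0.749 and erythroid markers at 0.758, and on replicate 1 oxidative phosphorylation genes at 0.774. Klf4 stood at 0.92 on Mst1KO S1_S2 replicate 2, Jaml at 0.893 on replicate 3 and Sbf2 at 0.945 on replicate 4. Fcer1g stood at 0.627 on WT S1_S2 replicate 2, Itga2 at 0.665 on WT S3 replicate 2, H2-Ob at 0.753 on WT S3 replicate 5 and Jup at 0.585 on WT S3 replicate 7.

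The Mst1KO effect at S3 minus that at S1_S2 was 1.77 for Eng, 1.64 for Ccr9, 1.24 for Pdlim1, 1.23 for Itga2, 1.14 for Mki67, 0.83 for S1pr1 and 0.58 for Fdps. It was -2.11 for Gzma, -1.55 for Ccr8, -1.37 for Ppp1r3b, -1.0 for Itgae, -0.98 for Slc24a3, -0.92 for Prrt1, -0.87 for Ly6c2, -0.81 for Ly6c1 and -0.56 for Cd7. For G1 to S phase genes the median was 0.52. Estimates of 2.12 for Ptprb, 1.63 for Kif15 and 1.33 for Cfap20dc are not measured sizes. Ptprb was above the negative controls in WT S1_S2 alone (5 of 6 arrays), Kif15 on 0 of 7 WT S3 arrays and Cfap20dc on no S3 array.

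dKOMst minus Mst1KO at S1_S2 was 2.16 for Gcsam and 2.03 for Tnni1, both dim and near the negative controls over all arrays. The difference was 2.02 for Sulf2, 1.96 for Fcer1g, 1.69 for H2-Ob, 1.60 for Jup and 1.03 for Sox4. It was -1.87 for Samd3, -1.29 for Bmp7, -1.26 for Itgae, -1.23 for Arsb, -1.14 for Slc16a6, -0.95 for Klf4, -0.89 for Rubcnl, -0.83 for Bcl2a1a, -0.72 for Bcl2a1d and -0.63 for Bcl2a1b. Npas4 (1.77) and Klrb1 (1.70), above the negative controls on 0 of 4 Mst1KO arrays, were higher by at least 1.12 and 0.71.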

How the results depend on the processing

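The tests on male arrays, with a sex term and with replicate numbers as a block were chosen only after the results were seen, and all others were planned.

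Between WT stages, 3760 clusters became 1388 at 1.5-fold or more, 965 in the first run and 1718 in the second. For Mst1KO at S1_S2, 116 became 56 with only the groups compared, 76 at 1.5-fold, 48 in the first run, 23 with male arrays and 69 with a sex term. For Mst1KO at S3, 1415 became 731 with no run term, 858 with the run as a random block, 5.0e+02 with only the groups compared, 420 at 1.5-fold, 336 in the first run and 475 with male arrays. For the Mst1KO stages, 2266 became 1093 at 1.5-fold and 953 with male arrays.

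For the difference of the Mst1KO effect between stages, 35 became 17 with no run term, 23 with only the groups compared, 55 with array weights, 23 with a sex term and 0 with male arrays (limma; 1504 at unadjusted p under 0.05). For dKOMst at S1_S2, 205 became 60 with only the groups compared, 325 with array weights, 343 with trend and robust variance and 100 in the second run. For dKOMst against Mst1KO, 38 became 195 with no run term, 81 with the run as a random block, 84 with array weights, 60 with trend and robust variance and 7 with male arrays. A fit of only those groups could not be run.

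With an estimated correlation the lists called were 13 for the WT stages, 2 and 5 for Mst1KO at S1_S2 and S3, 1 for the difference between stages, 3 for dKOMst at S1_S2 and 0 for dKOMst against Mst1KO. Fry called 7 for Mst1KO at S1_S2. For dKOMst at S1_S2, 7 were called with no run term and 7 over the brighter clusters, and for dKOMst against Mst1KO 7 with no run term. With no run term the camera direction reversed for 6 lists called with or without that term. Their medians then were -0.09 for G1 to S and -0.14 for G2 and M phase genes in Mst1KO at S1_S2, 0.05 for G2 and M phase genes in dKOMst at S1_S2, and 0.26 for G1 to S, 0.14 for G2 and M phase and 0.03 for oxidative phosphorylation genes in dKOMst against Mst1KO. The G2 and M phase calls at S1_S2 were lost too: in Mst1KO 0.045 became 0.91, 0.056 and 0.068 without WT replicates 1, 2 and 4 and 0.37 and 0.62 without Mst1KO replicates 1 and 3, and in dKOMst 0.0038 became 0.46 without dKOMst replicate 1 (limma camera adjusted p).

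On the dKOMst S3 array 204 clusters at 2-fold became 107 over the brighter clusters. A moderated limma test called 17 higher and 10 lower, but this group of 1 has no spread of its own and the test takes that of other groups. The set of clusters higher at WT S3 had a median of 0.13 in dKOMst at S1_S2 when chosen at 4-fold (p = 0.85) and 0.10 over the brighter clusters (p = 0.079), and the lower set -0.13 (p = 0.15 with an estimated correlation).

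With each array left out in turn, counts ran from 3362 to 3759, 66 to 174, 783 to 1399, 1670 to 2139, 14 to 61, 33 to 230 and 4 to 52 in the order above. The 66 and 14 came without Mst1KO S1_S2 replicate 2, the 174 and 61 without WT S1_S2 replicate 3, the 783 without Mst1KO S3 replicate 5, and the 33 and 4 without dKOMst S1_S2 replicate 1. Lists called ran from 20 to 23, 8 to 14, 11 to 14, 17 to 20, 8 to 14, 10 to 13 and 5 to 11.

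No label says that arrays share a mouse. With the replicate number as a replicate block (correlation -0.00561) the counts were 3744, 116, 1394, 2249, 33, 204 and 36. With title numbers a fixed step apart as a block the difference between stages had 53, and 2 of 10 such pairs had residual r over 0.1 (-0.11 to 0.17, and 0.056 to 0.17 in the 4 Mst1KO pairs). All 10 pairs were of the same sex, but every WT array had Y-linked signal, so only the 4 Mst1KO pairs could have differed.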

Other observations

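The tests on male arrays, of carried-over cells and against the negative controls were chosen only after the results were seen.

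Bcl2, which blocks mitochondrial cell death, rose by 1.71 ± 0.14 between the Mst1KO stages and by 1.34 ± 0.12 between the WT stages (limma adjusted p = 1.1e-08 and 9.3e-09). Survival and apoptosis genes had 5 of 17 members higher (7 adjusted over the list alone; median 0.22, camera adjusted p = 0.00068; 0.0058 with an estimated correlation), beside 6 of 17 in WT (7 adjusted over the list alone; median 0.16). The list mixes survival and death genes, and the death inducer gene Bcl2l11 rose too, by 0.53 ± 0.13 between the Mst1KO stages (limma adjusted p = 0.0076) and 1.20 ± 0.11 between the WT stages. NF-kB target genes had 5 of 17 higher in Mst1KO (7 adjusted over the list alone; median 0.28, adjusted p = 0.00034; 0.023 with an estimated correlation), including the costimulatory receptor gene Tnfrsf18 at 1.31 ± 0.10 against 1.30 ± 0.08 in WT.

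Over the same step in Mst1KO Itgb1 rose by 1.42 ± 0.12 and Itga4 by 1.23 ± 0.17, S1pr1 fell by 0.95 ± 0.13 and Itgae differed by -0.29 ± 0.15 (limma adjusted p = 0.23). Adhesion and egress genes had 9 of 18 members higher and 3 lower (9 and 3 adjusted over the list alone; median 0.29, limma camera adjusted p = 0.0023; 0.0091 with an estimated correlation). Cholesterol synthesis genes had 4 of 19 higher (6 adjusted over the list alone; median 0.27, limma camera adjusted p = 0.00047; 0.011 with an estimated correlation), including the regulator gene Srebf2 at 0.49 ± 0.11, whose limma adjusted p was 0.22 with male arrays. Between the WT stages that list had a median of 0.17 (limma camera adjusted p = 0.072). The NK cell adaptor genes Fcer1g and Tyrobp rose by 2.73 ± 0.19 and 2.51 ± 0.12 in Mst1KO (Fcer1g above the negative controls on 1 of 4 S1_S2 arrays), beside a median of 3.52 for NK receptors.

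Ccr9 changed by -2.64 ± 0.20 between the Mst1KO stages and by -4.29 ± 0.16 between the WT stages, a difference that passed (1.64 ± 0.25, limma adjusted p = 0.0058). Cdk1 changed by -1.62 ± 0.23 and -2.67 ± 0.19, a difference that did not (1.05, limma adjusted p = 0.2). A block late in maturation and a return to division are each possible. So is a small share of carried-over S1_S2 cells, 6.93% by the median of 13 genes (-4.94 to 12.4), with single genes from -118 to 30.7%. In Mst1KO at S3 the clusters higher at WT S3 had a median of -0.05, as had all clusters. The clusters lower at WT S3 had a median of 0.34, the direction that carried-over cells would give, but that set was not tested without cell cycle genes. How far a given share would lower the first set was not computed. These sets therefore do not decide whether carried-over cells account for the rise in cell cycle genes. Sorting with a marker independent of NK1.1, with DNA content measured, could test for carried-over cells and show whether S3 cells divide. It would not tell a block from a return to division.

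At S1_S2, Ly6c2, Csf1 and Atp8a2 differed in the same direction in Mst1KO and dKOMst in separate runs, although Csf1 in Mst1KO did not pass in its run (limma adjusted p = 0.065) and all changes correlated at only r = 0.132. Fos differed by 1.51 in Mst1KO and by -0.01 in dKOMst. The direct comparison of the knockouts for Fos (-1.30 ± 0.30, limma adjusted p = 0.069) did not pass, so a difference between them is not established. More dKOMst arrays in the same run as Mst1KO arrays would settle this, as 33 calls were left without dKOMst replicate 1.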
